A study of Macaca mulatta with 6 samples.

How the data were processed

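The series holds 6 Affymetrix Rhesus arrays of total RNA from peripheral blood monocytes of 2 uninfected macaques. Per the labels, the cells were sorted by flow cytometry into CD14+, CD14+CD16+ and CD16+ monocytes, 1 array per subset and animal. The labels name no further marker of the sort. Per the labels' protocols, RNA was taken up in Trizol, purified on a column and checked on a Bioanalyzer. Per the design text, each labelling started from 100 ng and used the 1-cycle or the 2-cycle amplification, and which array had which is not given in the sources used here. Per the same text and the submitters' processing notes, the authors scanned the arrays, made the values with GCOS and went on with Partek, in versions not given in the sources used here, and normalized the signals with the array's own normalization control probe sets. The deposited values are intensity signals on a linear scale, 1 per probe set and array, for 52865 probe sets. They span 0.0316 to 20254 over the 6 arrays, and the spike-in controls rise in the order of their concentrations. After the authors' normalization, array medians and spike-in signals still differed between arrays.

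Groups were taken from the sample titles, and same-numbered arrays come from the same animal, so replicates are separate animals. Probe sets were named through the platform annotation. Names on the gene lists that the array lacked were looked up among the synonyms of the RefSeq genes of assembly T2T-MMU8v2.0, which was used for names and the order of neighbouring genes only. Of the probe sets outside the 99 controls, 24956 had 1 gene symbol, 361 had several and 27449 had none, and those with several or none name no gene here. Of 604 names in the gene lists, 408 were matched on the array. CD163 is unnamed in this annotation and was not analysed here.

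The 99 control probe sets were left out of the fit. A probe set was kept if it lay above the 40th percentile of its array on at least 2 arrays, which left 38149, 19515 of them with 1 symbol, 301 with several and 18333 with none, for 11786 genes. Values were used as deposited, as log2(signal + 16). limma 3.58.1 in R 4.3.3 fitted group means over all 6 arrays (lmFit, then eBayes with an intensity trend, 3 residual degrees of freedom), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The contrasts were CD16+ minus CD14+, CD14+CD16+ minus CD14+, CD16+ minus CD14+CD16+, and CD14+CD16+ minus the mean of the other subsets, with a moderated F test over all 3. The position of CD14+CD16+ between the other subsets was computed in 1 animal over probe sets chosen in the other. A count of probe sets that differ at least 2-fold in both animals needs no estimate of the spread. The 3 comparisons share arrays in pairs, so no overlap or correlation between them is reported.

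The 25 gene lists were fixed before the data were examined, as were the design, the rule for named genes and the alternatives, except where the text says otherwise. One list is not reported, and the others are classical monocyte markers, nonclassical monocyte markers, MHC class II presentation, Fc and scavenger receptors, Toll-like receptor signalling, chemokines and cytokines, chemokine receptors and adhesion, interferon-stimulated genes, lentivirus entry and restriction factors, complement, lysosomal proteases and hydrolases, myeloid transcription factors, immediate early and heat shock genes, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis, cell cycle, NK and cytotoxic cells, T cells, B cells, neutrophils, platelets, dendritic cells and erythroid cells. Each list was tested against the other genes with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, with camera at an estimated correlation beside it. The rotation test fry, which asks whether the members of a list moved and not whether they moved more than other genes, was run as a further test, adjusted in the same way. In the estimated form no list passed in any comparison. That form rests on the 3 residual degrees of freedom of the fit, which keeps its p-values high even for lists whose members moved alike. Failing it therefore does not by itself argue against a list. A gene was represented by its kept probe set with the highest mean over all arrays. Named genes were 14 fixed monocyte genes, the 10 genes per direction and comparison with the largest change among those that passed and moved alike in both animals (where fewer passed, all of them, filled up to 5), up to 4 members per list and comparison with the smallest p, and the 5 smallest p-values of the midpoint contrast. The text prints part of them, and genes outside the rule are said to be chosen after their values were seen.

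Same-numbered arrays deviated together from their group means: the correlation of the animal differences over probe sets was 0.344 between CD14+ and CD14+CD16+, 0.262 between CD14+ and CD16+ and 0.336 between CD14+CD16+ and CD16+. The pairing comes from the labels, and the fit with the animal as a block (2 residual degrees of freedom) is given where it changes a call or a count by over 1.5 times.

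The fit was tested on simulated data for the comparison of CD16+ with CD14+, over 38149 probe sets, 20 runs and 200 changed probe sets, 50 of each size. It recovered 0% of 1.5-fold, 1.5% of 2-fold, 46.6% of 4-fold and 98.7% of 16-fold changes. In the data this comparison called 3051 probe sets, with a median absolute log2 difference of 1.55. With more changed probe sets the Benjamini-Hochberg cutoff is less strict, so the simulated recovery does not carry over to the data. Of the simulated calls, 5.05% were unchanged probe sets when spreads were drawn from the fitted distribution, and 13.5% when each probe set had its own moderated spread. A list shifted by 1 log2 passed in 20 of 20 runs with the preset and in 5 of 20 with the estimated correlation, and 0.15 other lists passed per run. The simulated probe sets varied independently of each other and without a difference between animals. In the data the estimated correlation of the NK list was 0.28, so these rates do not show how often the preset passes lists of correlated genes wrongly.

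Alternatives were pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization, median scaling, no intensity trend, the animal as a block or as a random block, probe sets without the _x_at and _s_at types, only the 4 arrays compared, and leaving out each array in turn. For the lists, the mean of all probe sets of a gene was used instead of the brightest, and members of several lists were left out. Scaling to the 27 hybridization spike-ins, median scaling applied to named genes, the block joined with quantile normalization and the comparison between the animals were chosen after seeing the data. With 2 arrays per subset, no test for outlying arrays and no count over other splits of the arrays was made. Animal identifiers and origin were left out.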

Results

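Messenger RNA was measured in 3 subsets of blood monocytes from 2 rhesus macaques that were negative for SIV, the simian immunodeficiency virus. The cells had been separated by flow cytometry on CD14, a co-receptor for bacterial lipopolysaccharide, and CD16, an IgG receptor that macaques encode in FCGR3. The sort gave CD14+ monocytes, double-positive CD14+CD16+ monocytes and CD16+ monocytes, and each subset of each animal went onto 1 Affymetrix Rhesus array. Every subset was therefore measured on 2 arrays, 6 in all, and this number limits the precision of each value below. The deposited signal had a median of 22.5 and 19.1 on the CD14+ arrays of animals 1 and 2, of 15.3 and 13.6 on the CD14+CD16+ arrays, and of 17.1 and 14.3 on the CD16+ arrays. Over the 38149 probe sets kept, the median log2 difference from CD14+ was -0.19 for CD16+ and -0.26 for CD14+CD16+ monocytes, and CD16+ minus CD14+CD16+ was 0.06. Shifts of gene lists are given relative to the median of all genes. The 3' to 5' signal ratio of the ACTB control, a sign of RNA quality, was 5.78 ± 1.06 in CD14+, 6.81 ± 0.63 in CD14+CD16+ and 7.90 ± 0.21 in CD16+ arrays (SD, n = 2). Signals are given as mean ± SD of the 2 arrays of a subset, log2 differences with their standard error (SE), and adjusted p-values from limma. Folds are on the log2(signal + 16) scale and understate the change of dim genes. Every gene named with a call moved in the same direction in both animals.

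**Figure D1:**
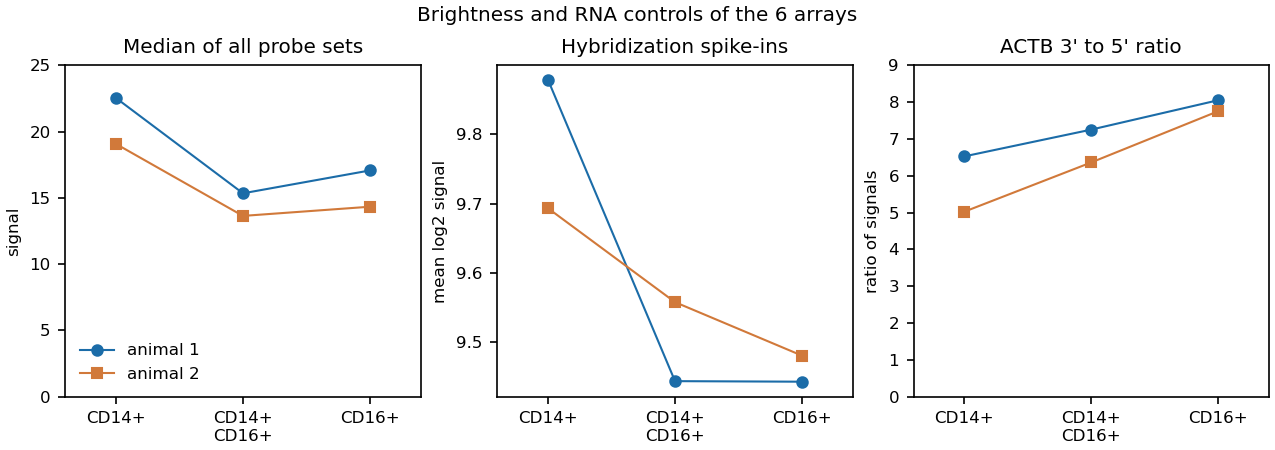
Median signal of all probe sets, mean log2 signal of the 27 hybridization spike-in probe sets and 3' to 5' signal ratio of ACTB, per array. Lines join the 3 arrays of an animal, and both CD14+ arrays had the highest medians (22.5 and 19.1) and the lowest ACTB ratio of their animal.

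The genes of both sorting proteins followed the sort, which checks the labels and is no finding about the subsets. CD14 signal was 1176 ± 118 in CD14+, 1127 ± 154 in CD14+CD16+ and 61.6 ± 15.3 in CD16+ monocytes. FCGR3 signal was 25.5 ± 11.9, 123 ± 7.20 and 309 ± 72.1 in the same order. The list counts and tests below include CD14 among the classical and Toll-like receptor genes. They include FCGR3 among the nonclassical markers and Fc receptors.

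The first comparison asked which genes separated CD16+ from CD14+ monocytes. S100A8 and S100A9, which together form calprotectin, fell, S100A8 from 3214 ± 891 to 4.20 ± 4.27 (159-fold, log2 difference -7.31, SE 0.32, adjusted p = 2.15e-06) and S100A9 by a log2 difference of -7.48 (178-fold, SE 0.39, adjusted p = 5.89e-06). SERPINB2, an inhibitor of plasminogen activators, fell from 13220 ± 2690 to 171 ± 41.8. CCL2, the chemokine that draws CCR2-bearing monocytes, fell from 4974 ± 696 to 45.0 ± 40.3 (92.0-fold, adjusted p = 1.74e-05). GNLY, encoding granulysin of cytotoxic granules, had the largest rise, from 27.9 ± 0.86 to 9566 ± 2245 (216-fold, log2 difference 7.75, SE 0.36, adjusted p = 2.63e-06). GZMB, encoding granzyme B, rose from 66.8 ± 30.2 to 8327 ± 120 (104-fold, adjusted p = 2.57e-06). C1QA and C1QB, which encode chains of the complement starter C1q, rose from 69.2 ± 7.85 to 5779 ± 4540 (56.8-fold, adjusted p = 0.000309) and from 14.6 ± 10.8 to 3697 ± 2679 (108-fold, adjusted p = 0.000102). The C1QA signal of the CD16+ arrays was 2569 in animal 1 and 8990 in animal 2, and its other probe set differed the other way (log2 difference -1.26, adjusted p = 0.108).

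Among the 10 genes with the largest rise were also GZMH (132-fold), METTL14 (59.4-fold), LOC722305 (47.3-fold), IFITM1 (36.0-fold), MAP6D1 (26.8-fold) and the chemokine gene CCL5 (25.2-fold). LOC722305 has no name of its own in the RefSeq assembly T2T-MMU8v2.0, where it lies between KLRB1 and DDX11. Of METTL14, an RNA methyltransferase subunit, 1 of 3 probe sets rose, and the others differed by log2 0.01 and -0.27 with no call. Besides those above, the largest falls were those of the matrix glycoprotein gene THBS1 (126-fold), the collagenase gene MMP1 (119-fold), MMP10 (73.3-fold), TREM1 (71.2-fold), CYP1B1 (63.9-fold) and NRG1 (63.8-fold). Several called genes had probe sets that did not all pass, and for these the brightest is reported. Among them were GNLY, C1QA, IFITM1, KLRC1, LOC722305, MS4A7, NR4A2, NRP1, SLC2A3, TLR4, TYMS, ICAM2, MERTK, OAS1, MAMU-DOB and EGR2.

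Classical monocyte markers, known from human CD14+ cells, fell as a group: 16 of 25 measured members fell and none rose, with a median of -1.32 relative to all genes (camera adjusted p = 1.01e-11, and adjusted p = 0.25 with an estimated correlation). Adjusted over the list alone, 18 fell and 1 rose. Beyond S100A8, S100A9, THBS1 and CYP1B1, S100A12 fell 20.7-fold (366 ± 101 to 2.11 ± 0.61, adjusted p = 4.94e-05) and the proteoglycan gene VCAN 3.74-fold (adjusted p = 0.00236). The chemokine receptor gene CCR2 fell from 87.6 ± 31.5 to 8.12 ± 4.73 (log2 difference -2.08, SE 0.41, adjusted p = 0.0127), a call that ended without CD14+ array 1 (adjusted p = 0.103), CD16+ array 1 (0.0535) or CD16+ array 2 (0.0916). Nonclassical markers rose as a group, with 11 of 30 members higher and 1 lower (adjusted p = 1.26e-10, and adjusted p = 0.25 with an estimated correlation), or 16 higher and 2 lower adjusted over the list alone. MS4A7, a membrane protein gene of the CD20 family, rose 21.3-fold (110 ± 14.1 to 2660 ± 239, adjusted p = 8.5e-06), the Wnt pathway transcription factor gene TCF7L2 6.37-fold (adjusted p = 8.96e-05) and LTB, a TNF family member, 7.68-fold (adjusted p = 0.000297). CX3CR1, the fractalkine receptor gene usually high in human nonclassical monocytes, was dim in all subsets and passed in none of the 3 comparisons between subsets (24.7 ± 8.13 in CD14+ and 20.1 ± 7.34 in CD16+, log2 difference -0.17, adjusted p = 0.802). CSF1R, the receptor gene for macrophage colony-stimulating factor, measured 742 ± 104 and 668 ± 237 (adjusted p = 0.757).

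Natural killer (NK) and cytotoxic cell markers rose with 11 of 15 members higher and none lower, and a median of 2.85 relative to all genes (adjusted p = 9.9e-12, and adjusted p = 0.25 with an estimated correlation). Adjusted over the list alone, 11 were higher and 3, KLRD1, GZMA and EOMES, lower. Besides GNLY, GZMB and GZMH, KLRC1, an NK receptor gene, rose 17.2-fold (5.28 ± 4.61 to 354 ± 104, adjusted p = 9.11e-05). Chosen after their values were seen, KLRD1 (1207 ± 261 to 740 ± 103, adjusted p = 0.141), GZMA (533 ± 54.8 to 319 ± 5.60, adjusted p = 0.127) and EOMES (57.5 ± 13.6 to 28.8 ± 5.99, adjusted p = 0.193) did not pass and were lower in both animals by their brightest probe sets. Their probe sets disagreed: 3 others of KLRD1 rose (log2 differences 2.73, 1.31 and 2.59, adjusted p = 0.00132, 0.0451 and 0.00108). The other of EOMES differed by log2 1.12 (adjusted p = 0.0625), and 1 of 3 others of GZMA fell (log2 difference -1.42, adjusted p = 0.0234). Of the T cell markers, ZAP70 (12.5-fold, adjusted p = 0.000626) and CD8A (11.9-fold, adjusted p = 0.000666), both also expressed by macaque NK cells, rose and the other 9 did not pass. The T cell list itself missed the threshold (adjusted p = 0.334, and 0.0418 without CD16+ array 2), with 3 members higher and 2 lower adjusted over the list alone. Cell cycle genes rose as a group beside these markers: 11 of 15 were higher, 13 adjusted over the list alone, and the median was 1.77 above all genes (adjusted p = 4.07e-11, and adjusted p = 0.25 with an estimated correlation). The cyclin genes CCNB2 (3.44 ± 1.68 to 164 ± 106, adjusted p = 0.00199) and CCNA2 (33.7 ± 5.46 to 258 ± 131, adjusted p = 0.00359) rose.

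Glycolysis genes fell, with 6 of 16 lower, 9 adjusted over the list alone (adjusted p = 0.00193, and adjusted p = 0.38 with an estimated correlation). The glucose transporter gene SLC2A3 fell 7.37-fold (11580 ± 1145 to 1554 ± 76.7, adjusted p = 6.99e-05), the phosphofructokinase gene PFKP 6.07-fold (adjusted p = 9.02e-05) and GAPDH 2.68-fold (5885 ± 1592 to 2148 ± 190, adjusted p = 0.00357). Interferon-stimulated genes passed upwards with 2 of 21 higher and 1 lower (adjusted p = 0.0281, and adjusted p = 0.296 with an estimated correlation), or 4 higher and 1 lower adjusted over the list alone. IFITM1 was among the higher members. The call ended without CD14+ array 2 (adjusted p = 0.0548), without CD16+ array 2 (0.0594) and with members of several lists left out (0.0611). Neutrophil markers passed downwards with 3 of 10 lower, 4 adjusted over the list alone (adjusted p = 0.0364, and adjusted p = 0.777 with an estimated correlation). The receptor gene CSF3R fell 8.35-fold (adjusted p = 0.000189), the gelatinase gene MMP9 28.2-fold (adjusted p = 0.000933) and the antimicrobial peptide gene CAMP 3.76-fold (adjusted p = 0.00106). The neutrophil call ended without CD14+ array 1 (adjusted p = 0.138), without CD16+ array 2 (0.0664) and with members of several lists left out (0.179).

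The other 16 lists given here missed the threshold in this comparison, though single members moved. Of 20 myeloid transcription factor genes, 3 rose and 6 fell (4 and 8 adjusted over the list alone, list adjusted p = 0.951), among them BATF3 (6.21-fold higher, adjusted p = 3e-04) and CEBPD (3.93-fold lower, adjusted p = 0.000933). Of 18 chemokines and cytokines, 2 rose and 5 fell (3 and 8 over the list alone, adjusted p = 0.849): IL15, a growth factor gene for NK cells, rose 6.36-fold and the cytokine gene OSM fell 16.5-fold. Of 16 chemokine receptor and adhesion genes, 4 rose and 4 fell (5 and 4, adjusted p = 0.961), with the chemokine receptor gene CCR1 9.49-fold and the anaphylatoxin receptor gene C5AR1 4.20-fold lower. Of 11 Fc and scavenger receptors, 1, the sorting gene FCGR3, rose and 4 fell (1 and 4, adjusted p = 0.562). MSR1, a scavenger receptor gene, was 7.71-fold and the IgA receptor gene FCAR 8.73-fold lower. Of 14 lysosomal genes, 3 rose and 3 fell (3 and 4, adjusted p = 0.849), with the protease gene CTSL 3.55-fold lower and CTSZ 3.32-fold higher. Of 12 complement genes, 3 rose and 1 fell (3 and 2, adjusted p = 0.224): the 3 C1q genes, C1QC among them at 14.3-fold, against C5AR1. Of 14 dendritic cell markers, 1 rose and 5 fell (2 and 7, adjusted p = 0.224, and 0.00329 with members of several lists left out), with the lectin gene CLEC10A 8.90-fold and the lipid antigen presenting molecule gene CD1B 12.6-fold lower.

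Of 16 Toll-like receptor genes, CD14 and TLR4, the lipopolysaccharide receptor gene, fell and none rose (0 and 3 adjusted over the list alone, list adjusted p = 0.952). TLR4 went from 5495 ± 1138 to 1257 ± 131 (adjusted p = 0.000367). Of 11 MHC class II presentation genes, 1 rose and 1 fell (1 and 1, adjusted p = 0.684). The alpha chain gene MAMU-DRA measured 11850 ± 209 and 9069 ± 1807 (log2 difference -0.40, adjusted p = 0.194), while another of its 3 probe sets fell (log2 difference -0.87, adjusted p = 0.0431). None of 10 lentivirus entry and restriction genes passed (0 and 0, adjusted p = 0.32). The SIV receptor gene CD4 measured 35.8 ± 9.24 and 72.8 ± 13.9 (log2 difference 0.78, SE 0.31, adjusted p = 0.165). Ribosomal protein genes had 2 higher and 1 lower of 21 (2 and 2, adjusted p = 0.676), oxidative phosphorylation genes 0 and 0 of 19 (0 and 0, adjusted p = 0.879), and immediate early and heat shock genes 0 and 1 of 13 (1 and 5, adjusted p = 0.154, and 0.0229 without CD16+ array 2). B cell markers had 0 higher and 1 lower of 11 (0 and 1, adjusted p = 0.951), platelet markers 0 and 2 of 12 (0 and 2, adjusted p = 0.684), and erythroid markers 0 and 0 of 5 (0 and 0, adjusted p = 0.922). The median, mean and test differed in sign for the Toll-like receptor, transcription factor, ribosomal, B cell, platelet and erythroid lists. By the rotation test fry, 6 of the 7 lists called by camera passed too (adjusted p from 0.00377 to 0.0312), neutrophil markers did not (0.0571), and platelet markers passed by fry alone (0.0312).

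In all, limma called 3051 of 38149 probe sets between CD16+ and CD14+ monocytes at an adjusted p under 0.05, 1005 higher and 2046 lower in CD16+. An unadjusted p under that level was reached by 8695. They stand beside an ACTB 3' to 5' ratio of 7.90 ± 0.21 in CD16+ and 5.78 ± 1.06 in CD14+ arrays. The split depended on the scaling: 1518 higher and 1422 lower with quantile normalization, 1557 and 1385 with median scaling, and, chosen after seeing the data, 1685 and 1280 with scaling to the spike-ins. With the animal as a block 7314 probe sets passed, and 1312 without CD14+ array 1, 1072 without CD16+ array 1 and 1474 without CD16+ array 2.

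**Figure D2:**
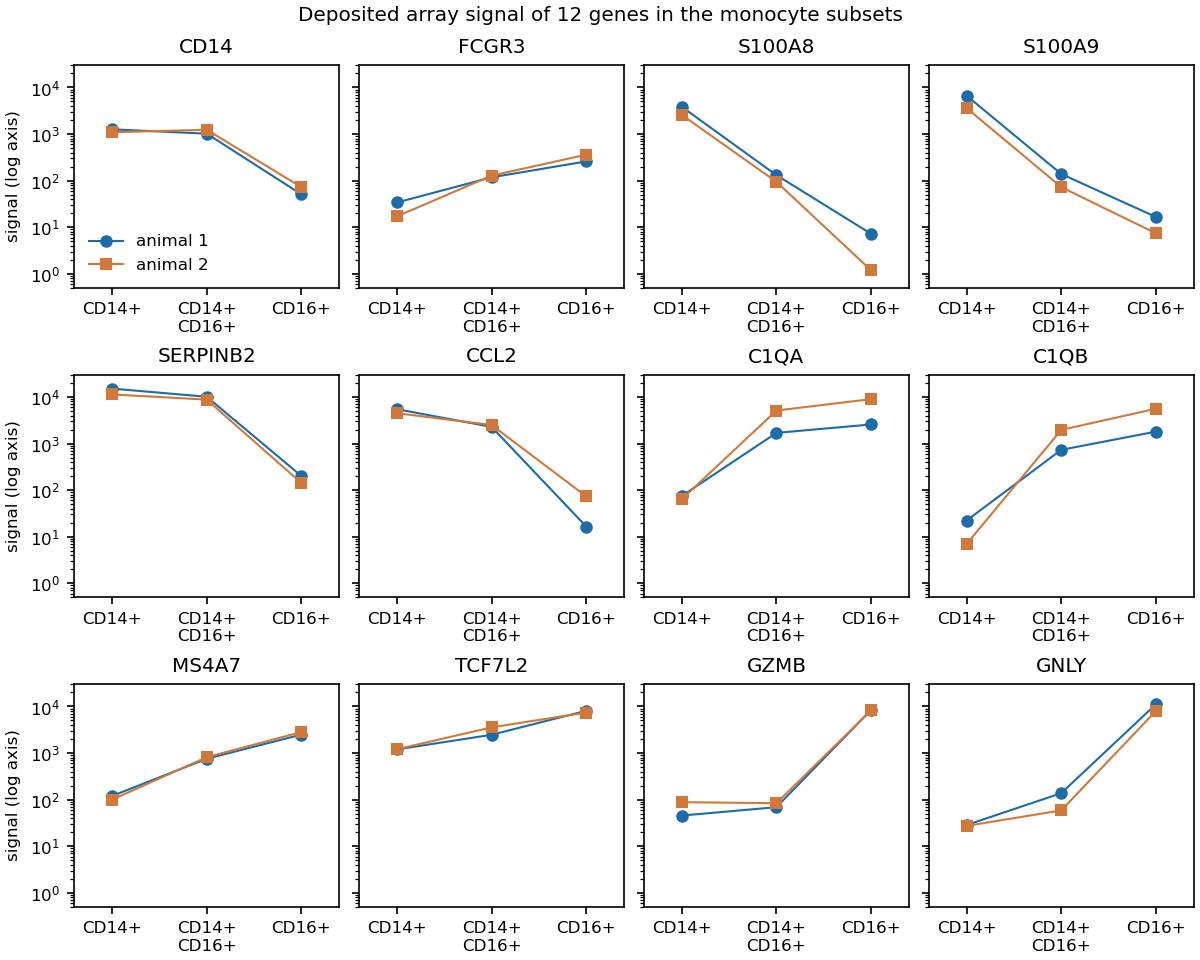
Deposited signal (log axis) of 12 genes in the 3 subsets, with 1 point per array and a line per animal. CD14, SERPINB2 and CCL2 dropped mainly between CD14+CD16+ and CD16+ monocytes, where GZMB and GNLY rose, while S100A8 and S100A9 were already lower in CD14+CD16+ monocytes.

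The second comparison asked what set double-positive CD14+CD16+ monocytes apart from CD14+ monocytes. S100A8 fell from 3214 ± 891 to 113 ± 26.1 (24.9-fold, log2 difference -4.64, SE 0.32, adjusted p = 0.00121) and S100A9 from 5139 ± 2154 to 106 ± 46.9 (42.0-fold, log2 difference -5.39, SE 0.39, adjusted p = 0.00121). C1QA rose from 69.2 ± 7.85 to 3401 ± 2416 (34.8-fold, log2 difference 5.12, SE 0.58, adjusted p = 0.0169). C1QB rose from 14.6 ± 10.8 to 1347 ± 870 (41.1-fold, adjusted p = 0.0169) and MS4A7 from 110 ± 14.1 to 784 ± 42.6 (6.38-fold, adjusted p = 0.00583). CD14 itself measured 1176 ± 118 and 1127 ± 154 (log2 difference -0.06, adjusted p = 0.935), and TLR4 5495 ± 1138 and 3886 ± 450 (adjusted p = 0.402). The calls of S100A8 and S100A9 held without any 1 of the 6 arrays. Those of C1QA and C1QB ended without CD14+ array 1 (adjusted p = 0.234 and 0.133), CD14+ array 2 (0.188 and 0.162) or CD14+CD16+ array 2 (0.154 and 0.152), and that of MS4A7 without CD14+ array 2 (0.0533) or either CD14+CD16+ array (0.0789 and 0.152).

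SELENOP, a selenium transport protein gene, rose 3.45-fold (adjusted p = 0.0293) and LY6D 4.61-fold (adjusted p = 0.0298). The atypical chemokine receptor gene ACKR3 fell 6.92-fold (532 ± 37.5 to 63.6 ± 13.8, adjusted p = 0.0169), MGST1, a glutathione transferase gene, 5.99-fold (adjusted p = 0.018), S100A12 5.80-fold (adjusted p = 0.0293), the calcium-binding grancalcin gene GCA 5.24-fold (adjusted p = 0.0293), QPCT 4.25-fold and the clotting factor V gene F5 4.16-fold (both adjusted p = 0.0488). The calls of SELENOP, LY6D, S100A12, GCA, QPCT and F5 ended without any 1 of the 6 arrays, at adjusted p-values from 0.0564 to 0.494. Those of ACKR3 and MGST1 ended without any 1 CD14+ or CD14+CD16+ array, at 0.154 to 0.251. Those of GCA, QPCT and F5 also ended with quantile normalization and, chosen after seeing the data for named genes, median and spike-in scaling (adjusted p from 0.052 to 0.0939). A pseudocount of 1 ended those of S100A12, SELENOP, MGST1, GCA, QPCT and F5 (0.0516 to 0.221). Of C1QA, MGST1 and MS4A7, other probe sets did not pass, and that of C1QA differed the other way (log2 difference -0.81, adjusted p = 0.455).

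Classical monocyte markers fell as a group, with 5 of 25 lower and none higher (camera adjusted p = 6.94e-08, and adjusted p = 0.187 with an estimated correlation), and 10 lower adjusted over the list alone. Nonclassical markers rose, with 3 of 30 higher, 8 adjusted over the list alone (adjusted p = 1.05e-15, and adjusted p = 0.187 with an estimated correlation). FCGR3 missed the threshold (log2 difference 1.77, SE 0.32, adjusted p = 0.174). It passed with the animal as a block (0.00187). BATF3 measured 89.5 ± 3.19 and 348 ± 13.4 (adjusted p = 0.0595, 0.000159 with the block and 0.0368 with quantile normalization), and TCF7L2 1201 ± 5.32 and 3014 ± 773 (adjusted p = 0.113, 0.000873 with the block and 0.0375 with quantile normalization). The complement list passed upwards with C1QA and C1QB alone higher of 12, and 5 adjusted over the list alone, while 6 members were higher and 4 lower in both animals (adjusted p = 2.66e-07, and adjusted p = 0.19 with an estimated correlation).

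A further 5 lists passed although none of their members did. Interferon-stimulated genes lay above the other genes (median 0.37 relative to them, adjusted p = 0.000319, and adjusted p = 0.187 with an estimated correlation). MHC class II genes lay above them too (median 0.32, adjusted p = 0.0285, and adjusted p = 0.64 with an estimated correlation), but not without CD14+ array 1 (0.252) or CD14+CD16+ array 2 (0.41). CD74, the invariant chain gene, measured 2378 ± 275 and 3245 ± 851 (adjusted p = 0.522). Cell cycle genes passed upwards (median 0.25, adjusted p = 0.0285, and adjusted p = 0.72 with an estimated correlation), but not with quantile normalization (0.144), the mean of all probe sets of a gene (0.216), or without CD14+ array 1 (0.263), CD14+CD16+ array 1 (0.0887) or CD14+CD16+ array 2 (0.0626). Glycolysis genes lay lower (median -0.30, adjusted p = 0.00199, and adjusted p = 0.459 with an estimated correlation), with 2 lower adjusted over the list alone and SLC2A3 at 6056 ± 1866 (adjusted p = 0.253, and 0.00566 with the block). Neutrophil markers lay lower (median -0.41, adjusted p = 0.0387, and adjusted p = 0.72 with an estimated correlation), with 2 lower adjusted over the list alone, but not without CD14+ array 1 (0.485), CD14+CD16+ array 2 (0.249) or with members of several lists left out (0.178). NK markers missed the threshold (0 of 15 passing, 1 higher and 1 lower adjusted over the list alone, adjusted p = 0.29). GNLY measured 27.9 ± 0.86 and 98.1 ± 55.7 (adjusted p = 0.289, and 0.0058 with the block). None of the other 15 lists given here passed either, at adjusted p-values from 0.158 to 0.808. Lysosomal genes did pass with quantile normalization (0.0198) and myeloid transcription factors with members of several lists left out (0.0191). Median, mean and test differed in sign for the Fc receptor, chemokine, ribosomal and B cell lists. By the rotation test fry, only classical markers passed of the 8 lists called by camera (adjusted p = 0.0285). The other 7 did not (0.0602 for glycolysis to 0.928 for the cell cycle), and chemokine receptors and adhesion passed by fry alone (0.0285).

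In all, 23 of 38149 probe sets passed in CD14+CD16+ against CD14+ monocytes, 9 higher and 14 lower, and 4680 had an unadjusted p under 0.05. The split was 15 and 7 with quantile normalization, 13 and 7 with median scaling and 16 and 9 with spike-in scaling. With the animal as a block 1669 passed, 166 higher and 1503 lower, or 391 and 302 where the block was joined, after seeing the data, with quantile normalization. Without 1 array, 4 (CD14+ array 1), 3 (CD14+ array 2), 5 (CD14+CD16+ array 1), 2 (CD14+CD16+ array 2) and 12 (either CD16+ array) passed.

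The third comparison asked what set CD16+ apart from double-positive monocytes. CD14 fell from 1127 ± 154 to 61.6 ± 15.3, as the sort required. SERPINB2 fell from 9439 ± 941 to 171 ± 41.8 (51.0-fold, log2 difference -5.67, SE 0.23, adjusted p = 3.31e-06), CCL2 from 2388 ± 157 to 45.0 ± 40.3 (44.5-fold, adjusted p = 9.48e-05) and TREM1, an amplifier of inflammatory signalling, from 1871 ± 212 to 50.3 ± 35.2 (30.6-fold, adjusted p = 9.11e-05). GZMH rose from 46.2 ± 3.09 to 6873 ± 982 (110-fold, log2 difference 6.78, SE 0.27, adjusted p = 3.31e-06). GZMB rose from 76.3 ± 10.6 to 8327 ± 120 (90.7-fold, adjusted p = 6.37e-06) and the cytotoxic granule gene NKG7 from 16.4 ± 9.82 to 688 ± 208 (21.7-fold, adjusted p = 0.000172). TGFBR3, a TGF-beta co-receptor gene, rose 23.7-fold (adjusted p = 8.44e-05). CD200R1, an inhibitory receptor gene, fell from 822 ± 325 to 24.4 ± 3.90 (log2 difference -4.32, adjusted p = 0.000369).

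The remaining genes with the largest rises were GNLY (88.3-fold), LOC722305 (61.2-fold), IFITM1 (29.4-fold), MAP6D1 (25.1-fold), METTL14 (21.5-fold) and CCL5 (21.3-fold). Those with the largest falls were THBS1 (49.4-fold), MMP1 (48.5-fold), CYP1B1 (47.0-fold), NRG1 (31.8-fold), CD1B (21.0-fold) and MMP10 (21.0-fold). Among the called genes whose probe sets did not all pass were GNLY, IFITM1, KLRC1, LOC722305, METTL14, MMP1, MS4A7, SLC2A3, TCF7L2, THBS1, TLR4, CCNA2, MAMU-DMA, ICAM2, IL15 and CDK1.

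Classical markers fell, with 9 of 25 lower and none higher (camera adjusted p = 4.71e-12, and adjusted p = 0.307 with an estimated correlation), or 13 lower and 1 higher adjusted over the list alone. S100A8 fell 6.38-fold (adjusted p = 0.00211) and QPCT, glutaminyl cyclase, 6.28-fold (adjusted p = 0.00125). CCR2 missed the threshold (68.1 ± 45.0 to 8.12 ± 4.73, adjusted p = 0.0588), and passed with the block (0.000653), with a pseudocount of 1 (0.0436), with quantile normalization (0.0364), with median scaling, chosen after seeing the data for this gene (0.0351), and without CD14+CD16+ array 2 (0.0426). Nonclassical markers rose with 5 of 30 higher, 12 adjusted over the list alone (adjusted p = 0.00132, and adjusted p = 0.609 with an estimated correlation), but not with members of several lists left out (0.0967). LTB rose 4.56-fold (adjusted p = 0.00343, and 0.0508 without CD16+ array 1) and MS4A7 3.34-fold (adjusted p = 0.00466, and 0.0597 without CD14+CD16+ array 1, 0.0534 without CD16+ array 1 and 0.0558 without CD16+ array 2).

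NK markers rose with 10 of 15 higher, 11 adjusted over the list alone, and a median of 2.54 relative to all genes (adjusted p = 5.78e-14, and adjusted p = 0.4 with an estimated correlation). The brightest probe sets of KLRD1 and EOMES had no call, while 3 others of KLRD1 (log2 differences 2.91, 1.73 and 2.64, adjusted p = 0.00211, 0.0255 and 0.00212) and 1 of EOMES (2.02, adjusted p = 0.00887) rose. CD8A (17.7-fold, adjusted p = 0.000642) and ZAP70 (15.0-fold, adjusted p = 0.000946) rose beside them. The T cell list missed the threshold with 2 of 11 higher, 3 adjusted over the list alone (adjusted p = 0.0518, 0.0439 with the block, 0.0416 with the mean of all probe sets of a gene, 0.0375 without CD14+CD16+ array 1 and 0.00263 without CD16+ array 2). Cell cycle genes rose with 8 of 15 higher, 13 adjusted over the list alone (adjusted p = 2.63e-09, and adjusted p = 0.41 with an estimated correlation). CCNA2 rose 5.21-fold (adjusted p = 0.00744, and 0.0769 without CD16+ array 1 and 0.07 without CD14+CD16+ array 2).

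MHC class II genes fell as a list with 1 of 11 lower, 3 lower and 1 higher adjusted over the list alone (adjusted p = 0.0207, and adjusted p = 0.609 with an estimated correlation). MAMU-DMA, a chain of the peptide exchange factor, measured 8029 ± 515 and 4375 ± 805 (adjusted p = 0.0271), a call that ended without any 1 CD14+CD16+ or CD16+ array (0.0531 to 0.283). CD74 measured 3245 ± 851 and 1730 ± 514 (adjusted p = 0.113, and 0.00126 with the block). Glycolysis genes passed downwards with 2 of 16 lower and 1 higher (adjusted p = 0.0207, and adjusted p = 0.609 with an estimated correlation), or 5 lower and 1 higher adjusted over the list alone, with SLC2A3 3.78-fold lower (adjusted p = 0.00172). Dendritic cell markers passed downwards with 3 of 14 lower and 1, GZMB, higher (adjusted p = 0.0207, and adjusted p = 0.609 with an estimated correlation), or 6 lower and 2 higher adjusted over the list alone. These 3 calls ended with quantile normalization (adjusted p = 0.0971, 0.0942 and 0.0688 in this order), without CD16+ array 1 (0.158, 0.0685 and 0.0685) and without CD14+CD16+ array 2 (0.194, 0.0728 and 0.147). The other 16 lists given here missed the threshold, the lowest after the T cell list being neutrophil markers (adjusted p = 0.0975, and 0.03 with the mean of all probe sets of a gene). Fc and scavenger receptors (adjusted p = 0.245) passed with that mean (0.0251), and chemokines and cytokines (adjusted p = 0.32) without CD14+CD16+ array 1 (0.0375) or CD16+ array 2 (0.0217). Median, mean and test differed in sign for the Toll-like receptor, chemokine receptor, interferon, transcription factor, oxidative phosphorylation, B cell and platelet lists. By the rotation test fry, classical and NK markers passed (both adjusted p = 0.0131), and the other 5 lists called by camera did not (0.0726 for the cell cycle to 0.693 for dendritic cell markers). Among members of the lists that missed it, the scavenger receptor gene MSR1 fell 5.66-fold (adjusted p = 0.00225), CCR1 fell 7.49-fold (adjusted p = 0.00173) and the myeloid and lymphoid transcription factor gene GFI1 rose 9.52-fold (adjusted p = 0.00561).

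In all, 1168 of 38149 probe sets passed in CD16+ against CD14+CD16+ monocytes, 692 higher and 476 lower, and 5772 had an unadjusted p under 0.05. The split was 627 and 628 with quantile normalization, 625 and 598 with median scaling and 882 and 537 with spike-in scaling. With the animal as a block 4400 passed, and without 1 array 328 (CD14+CD16+ array 1), 393 (CD14+CD16+ array 2), 271 (CD16+ array 1) and 525 (CD16+ array 2).

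**Figure D3:**
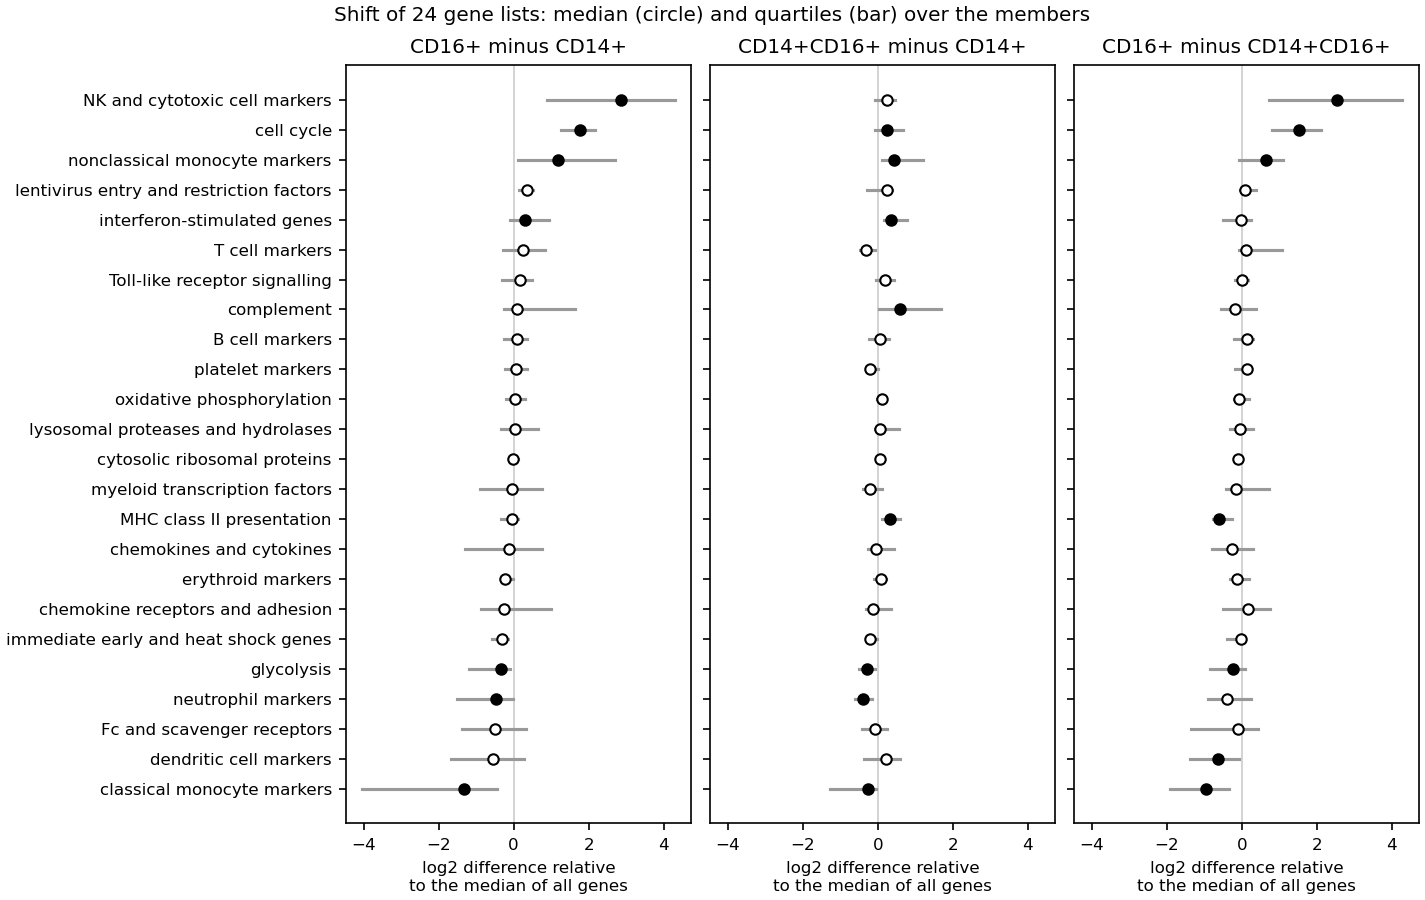
Median (circle) and quartiles (bar) of the log2 differences of the members of 24 gene lists, relative to the median of all genes, in the 3 comparisons. Filled circles passed camera with its preset correlation, none passed with an estimated one, and NK markers had the highest medians in both comparisons of CD16+ monocytes (2.85 and 2.54).

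A last contrast asked whether double-positive monocytes lay off the midpoint between the other subsets on the log2 scale. The 5 genes with the smallest p-values were GZMH, SERPINB2, LOC722305, GZMB and NRG1. GZMH lay below the midpoint in CD14+CD16+ monocytes (46.2 ± 3.09 against 36.0 ± 3.58 in CD14+ and 6873 ± 982 in CD16+, log2 difference -3.26, SE 0.23, adjusted p = 0.00136), as did LOC722305 (log2 difference -3.15, adjusted p = 0.00136) and GZMB (-3.15, adjusted p = 0.00154). SERPINB2 lay above it (log2 difference 2.60, SE 0.20, adjusted p = 0.00136), as did NRG1, an EGF family growth factor gene (961 ± 150 against 1932 ± 21.0 in CD14+ and 14.6 ± 1.12 in CD16+, log2 difference 1.99, adjusted p = 0.0134). NRG1 lost its call without CD14+ array 2 (adjusted p = 0.0554), CD14+CD16+ array 1 (0.142) or CD14+CD16+ array 2 (0.261). For all these genes the double-positive value was nearer to the CD14+ value on the log2(signal + 16) scale. The contrast passed for 43 probe sets, 16 above and 27 below the midpoint, and 3708 had an unadjusted p under 0.05. The split was 31 and 23 with quantile normalization, 34 and 25 with median scaling and 30 and 28 with spike-in scaling. With the block 1214 passed, and without 1 array 20 and 13 (CD14+ arrays 1 and 2), 8 and 5 (CD14+CD16+ arrays 1 and 2), 23 and 69 (CD16+ arrays 1 and 2). An F test over the 3 subsets passed for 2256 probe sets (5.91%), 7495 with the block, and 1247 without CD14+ array 1, 536 without CD16+ array 1 and 857 without CD16+ array 2.

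Over the genes that differed by at least 1 log2 between CD14+ and CD16+ monocytes in one animal, the double-positive subset of the other animal lay at a median of 0.39 (animal 1, 5229 probe sets) and 0.35 (animal 2, 7080) of the way from CD14+ to CD16+. For those higher in CD16+ monocytes the median position was 0.073 and 0.11, and for those lower 0.52 and 0.42. The same CD14+ array enters both parts of this ratio. Probe sets whose difference did not recur in the other animal therefore pull the median towards the midpoint, by an amount that was not estimated. Of the 10 largest falls, S100A8 and S100A9 lay at 0.63 and 0.72 and the other 8 from 0.074 (CYP1B1) to 0.29 (MMP10). For genes near background in 1 subset, such as S100A8 in CD16+ monocytes, the position depends on the pseudocount. Of the 10 largest rises, C1QB and C1QA lay at 0.79 and 0.88 and the other 8 from -0.067 (LOC722305) to 0.25 (METTL14). With quantile normalization the positions of these groups were alike, at 0.28 and 0.24 for higher and 0.30 and 0.26 for lower probe sets. With a pseudocount of 1 they were 0.24 and 0.27 for higher and 0.54 and 0.46 for lower ones. As a rule of size without a test, 2827 probe sets differed at least 2-fold in the same direction in both animals between CD16+ and CD14+ (971 higher, 1856 lower), 601 between CD14+CD16+ and CD14+ (66 and 535, 343 in all with quantile normalization) and 1776 between CD16+ and CD14+CD16+ (1069 and 707).

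**Figure D4:**
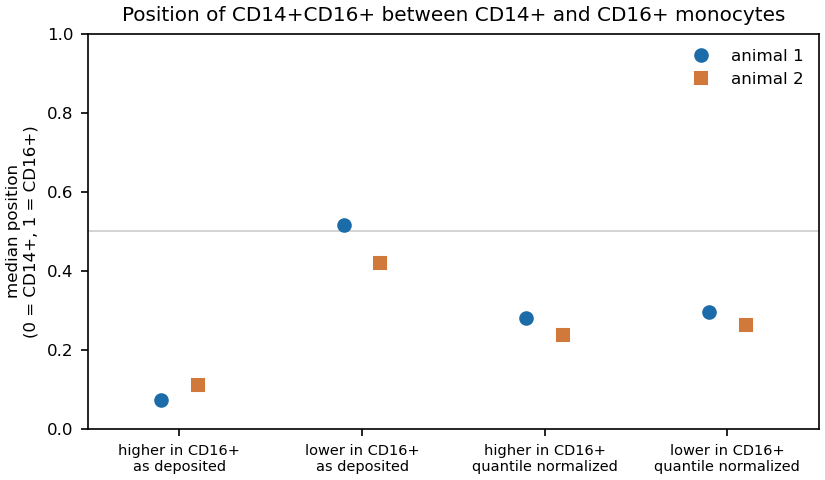
Median position of CD14+CD16+ between CD14+ (0) and CD16+ (1) monocytes on the log2 scale, for probe sets higher and lower in CD16+ monocytes, with 1 point per animal. As deposited, higher probe sets lay at 0.073 and 0.11 and lower ones at 0.52 and 0.42, and after quantile normalization all 4 values lay between 0.24 and 0.30.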

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

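The tests of array brightness in this part were chosen only after the differences between arrays had been seen. The values of this paragraph come from control probe sets that were left out of the fits, and the hybridization spike-ins served only for 1 alternative scaling. The 27 hybridization spike-in probe sets, which measure bacterial RNA added to each array and hold no monocyte RNA, were dimmer on the CD16+ than on the CD14+ arrays, with a mean log2 difference of -0.32 (SD 0.089 over the probe sets, -0.43 in animal 1 and -0.21 in animal 2). Between CD14+CD16+ and CD14+ arrays the difference was -0.28 (SD 0.12, -0.43 and -0.14). The 3' to 5' signal ratio of ACTB had its highest mean on the CD16+ arrays, 7.90 ± 0.21 (SD, n = 2), against 5.78 ± 1.06 on the CD14+ arrays, while that of GAPDH was 2.31 ± 0.34 against 2.09 ± 0.078. The poly-A spike-ins, added before labelling, were brighter in animal 2 than in animal 1 by a mean log2 difference of 0.99. Between subsets they differed by 0.030 for CD16+ minus CD14+ (-0.066 and 0.13 in animals 1 and 2) and by -0.39 for CD14+CD16+ minus CD14+ (-0.78 and -0.0087).

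The CD14+ arrays were brighter than the others over the 38149 probe sets kept, by medians of log2 -0.19 for CD16+ and -0.26 for CD14+CD16+ with the pseudocount, and -0.30 and -0.39 without one. Brightness of the whole array left over from the normalization would shift spike-ins and probe sets alike, within 0.1. For CD16+ the median lay 0.13 above the spike-in difference with the pseudocount and 0.022 above it without, and for CD14+CD16+ 0.021 above and -0.11 from it. The spike-in difference was taken without a pseudocount, and the pseudocount shrinks differences of dim probe sets. Only the measure without one is therefore on the scale of the spike-ins. The poly-A spike-ins did not share the shift of the hybridization spike-ins for CD16+ in either animal (-0.066 and 0.13 against -0.43 and -0.21). Their difference of 0.99 between the animals, for a reason that was not tested, drops out of these values. They were added before labelling and so also passed through it, with an amplification that is not given per array. They therefore do not decide whether the whole array was dimmer there. The measure without a pseudocount was added after the first had been seen, and by it the gap was within 0.1 for CD16+ and beyond 0.1 for CD14+CD16+. The verdicts swap with the measure in both comparisons, in part because of the scale. On the scale of the spike-ins, brightness of the whole array could account for the CD16+ median (-0.30 against -0.32). For CD14+CD16+ the median lay below the spike-ins (-0.39 against -0.28). A lower messenger RNA content of the subsets would not by itself dim the hybridization spike-ins, which hold no monocyte RNA. Whether it also shifted the probe sets cannot be told apart here and was not tested. Which arrays had the 1-cycle or the 2-cycle amplification is not given in the sources used here, and if it differed between subsets, part of the differences in brightness and in the ACTB ratio could come from it.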

How the results depend on the processing

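Scaling to the spike-ins, median scaling for named genes and the replicate block joined with quantile normalization were chosen after seeing the data, and all other alternatives before. The numbers of calls in CD16+ against CD14+, CD14+CD16+ against CD14+, CD16+ against CD14+CD16+, the midpoint contrast and the F test were 3051, 23, 1168, 43 and 2256. In the same order they were 7314, 1669, 4400, 1214 and 7495 with the animal as a replicate block, 5047, 79, 2434, 184 and 4197 with it as a random block (correlation 0.184), and 7137, 693, 4973, 1058 and 6827 with the replicate block and quantile normalization. All calls of the 4 contrasts without the block were kept with it. Counts for CD14+CD16+ against CD14+ dropped to 10 with a pseudocount of 1, 5 with no filter, 14 with the 60th percentile filter, 8 with no intensity trend and 9 with only the 4 arrays compared. The midpoint contrast dropped to 23 with a pseudocount of 1, 24 with no filter and 27 with no intensity trend. No filter, which tests more probe sets, gave 769 calls for CD16+ against CD14+CD16+ and 1465 for the F test. Leaving out each array in turn gave ranges of 1072 to 2614, 2 to 12, 271 to 1243, 5 to 69 and 536 to 2002 calls, where the lone array of a subset was assumed to vary like the other groups. Probe sets that differed at least 2-fold in both animals numbered 6022, 3435 and 4450 in the 3 comparisons with a pseudocount of 1, and 1498, 175 and 830 with one of 64, which compresses dim signals by construction, and quantile normalization gave 343 for CD14+CD16+ against CD14+. The position of CD14+CD16+ moved from 0.39 and 0.35 in animals 1 and 2 to 0.46 and 0.41 with a pseudocount of 1, to 0.29 and 0.25 with quantile normalization, and to 0.30 in animal 2 with a pseudocount of 64. The numbers of lists past the threshold, 7, 8 and 7, were 0, 0 and 0 with an estimated correlation, and quantile normalization gave 4 for CD16+ against CD14+CD16+. Leave-one-out ranges of these numbers were 6 to 7, 5 to 8 and 4 to 9. Of 334 calls and values of named genes, the block moved 87 past the threshold and ended none, quantile normalization moved 11 past it and ended 7, a pseudocount of 1 moved 1 and ended 9, and one of 64 moved 6 and ended 4. Median scaling moved 9 and ended 6, and spike-in scaling moved 15 and ended 6. No direction reversed where either fit made a call, and changes of sign among uncalled values were not counted. Apart from the calls given with the results, the block changed no list call. The causes were not tested except where stated. Signals near background limit what can be said of dim genes such as CX3CR1.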

Other observations

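The comparison of the animals and the test on cell cycle genes below were chosen after the data were seen, and the prediction for NK cells was written before. In the fit with the animal as a block, 2310 probe sets differed between the 2 animals over the 3 subsets, 802 higher and 1508 lower in animal 2 (7244 with an unadjusted p under 0.05). Array medians were lower in animal 2 in every subset (19.1 against 22.5 in CD14+, 13.6 against 15.3 in CD14+CD16+, 14.3 against 17.1 in CD16+). The split was not computed with another scaling, so part of it may follow brightness. USP14, a deubiquitinase gene, measured 8513, 5764 and 7876 in CD14+, CD14+CD16+ and CD16+ monocytes of animal 1 and 410, 412 and 120 in animal 2 (log2 -4.64, SE 0.26, adjusted p = 1.01e-08). The sulfotransferase gene CHST15 was lower in animal 2 by log2 -3.21 (SE 0.17, adjusted p = 6.37e-09). GPR183, an oxysterol receptor gene, measured 776, 777 and 219 in animal 1 and 3221, 2572 and 832 in animal 2 (log2 1.86, SE 0.14, adjusted p = 7.3e-07). The killer cell receptor gene KIR3DL12 measured 3151, 1567 and 244 in animal 1 and 779, 383 and 95.5 in animal 2 (log2 -1.74, SE 0.17, adjusted p = 1.62e-05). With 1 animal on each side these differences belong to 2 animals, and they were not traced to sequence, condition or handling.

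NK and cytotoxic cell markers rose as a list in CD16+ against CD14+ monocytes, with 11 of 15 members called (adjusted p = 0.25 with an estimated correlation). NK cells carry CD16, and the labels name no marker beyond CD14 and CD16, so NK cells within the CD16+ gate could explain the rise. That predicts a median shift of the list upwards relative to all genes, with most members higher in both animals. The shift was log2 2.85, and 12 of 15 members, 80%, were higher in both animals, but the test reads the same list that shows the rise, and expression by the monocytes would give the same outcome, so the explanation cannot be told apart from it. By their brightest probe sets KLRD1, GZMA and EOMES were lower in both animals, but 3 other probe sets of KLRD1 rose and the other of EOMES differed by log2 1.12 (adjusted p = 0.0625), while another of GZMA fell (adjusted p = 0.0234). The brightest probe sets of KLRD1, GZMA and NCR3 were already at 1207, 533 and 332 in CD14+ monocytes, where a small share of NK cells might not show. KIR3DL12, a receptor gene of NK cells outside the list and chosen after its values were seen, was lower in CD16+ than in CD14+ monocytes (log2 -3.22, adjusted p = 0.023). It rests on 1 probe set of the less specific _x_at type, so it decides nothing. GNLY, GZMB and GZMH reached 9566, 8327 and 6873. Expression of these genes by CD16+ monocytes themselves was not tested and stays open.

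Cell cycle genes also rose as a list in CD16+ against CD14+ monocytes (adjusted p = 0.25 with an estimated correlation), and dividing cells among NK cells of the gate could carry them. In that case the cell cycle and NK lists would differ alike between the 2 CD16+ arrays. Animal 1 minus animal 2, the list medians were log2 0.66 and 0.41, apart by 0.25 (SE 0.20). This SE is that of a difference of means, with the 15 members of each list taken as independent. It does not measure the spread between animals, each of which has 1 CD16+ array. The gap cannot be told apart from no difference, and the rule for it was set after a first look. Division of the monocytes themselves may contribute and was not tested.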
